A study of Mus musculus with 2 samples.

How the data were processed

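H3K4me2, a histone modification found at promoters and enhancers, was profiled by ChIP-seq in hindbrain of mouse embryos at 16.5 days (strain B6NCrl). There were 2 biological replicates, each a pool of male and female embryos. Replicate 2 was pooled from 37 embryos per the labels, and the pool size of replicate 1 is not given in the sources used here. The labels call them biological replicates but give both the same donor identifier, and whether the pools were collected separately is not stated. SDs with n = 2 therefore describe only the spread between these samples, which may be technical. Both replicates belong to 1 group, so no treatment or tissue is compared. The comparisons are between the replicates, between parts of the genome and between gene lists.

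The 4 deposited peak lists, on mm10, were a list per replicate, a list called on both replicates pooled, and a replicated list that the authors derived from these 3. Each peak carries an enrichment that the authors computed as a ratio, and a −log10 p and a −log10 q from the authors' peak call, per the deposited file descriptions. What the enrichment is relative to is not stated. The lowest −log10 p was just over 2 in each list. The peak caller, its version and the rule for replicated peaks are not given in the sources used here. Per the deposited file descriptions, the replicate 1 call was made from its alignment and 2 further files, and the replicate 2 call from its alignment and 1 of the same further files. What these further files hold is not stated. Alignments and signal tracks were not analysed here. Depth in reads is unknown, so weak peaks cannot be weighed by read number, and a longer list may come from more reads.

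Peaks on chromosomes 1 to 19, X and Y were kept. This left out 19 peaks of the replicate 1 list and 17 of the replicate 2, 18 of the pooled and 17 of the replicated list. Genes came from the GENCODE M21 basic annotation of GRCm38, the same assembly as mm10. The 21851 protein-coding genes had 41438 transcription start site (TSS) positions, from protein-coding transcripts. A gene was called marked when a peak overlapped 1 kb either side of any of its TSSs. Breadth was the number of base pairs covered by peaks within 5 kb either side of a TSS, taking the highest TSS of the gene. Distal peaks lay over 2 kb from every protein-coding TSS, and were counted within 50 kb of a gene's TSS. Domains were replicated peaks stitched when within 1 kb of each other. Broad domains were the longest 5% of these.

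A peak was found in the other replicate when at least 50% of its length was covered there. Expected overlap and location came from 100 random placements of the peaks within their chromosomes (bedtools 2.31.1). A total of 32 gene lists were fixed before the data were examined, among them markers of other cell types and tissues. One erythroid gene, Ahsp, had no match in the annotation. Lists were compared with all other protein-coding genes by two-sided Fisher exact tests for marking. For broad domains, marked members were compared with all other marked genes by the same test. Breadth and distal peaks were compared with 10000 random lists of the same size, called the list permutation test below. These were drawn from marked genes for breadth and from all protein-coding genes for distal peaks. The p-values were adjusted over the lists by the Benjamini-Hochberg method and called at 0.05. The smallest unadjusted p that the list permutation test can give is 0.0002. Differences of mean breadth were tested by a two-sided permutation test with 100000 resamples. For 13 motifs, the 400 bp around the middle of each distal peak were compared with a window starting 2 kb downstream that held no peak, by an exact McNemar test. Genes and peaks are not replicates, so these p-values describe these libraries only. Shares have 95% Wilson intervals, which cover counting error only. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

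Genes named in the text are those with a TSS in the 20 longest domains, in each list the 3 members with the largest breadth and up to 2 unmarked members, alphabetically first, the Hox genes as a group, and up to 10 list members marked in 1 replicate only. The tests were tested on simulated data over the 21851 genes. Of simulated lists of 20 independent genes marked at 98% against 66%, 96.5% were recovered and 0% of unchanged lists were called. Of lists with doubled breadth, 90.5% were recovered, and 3.5% of unchanged lists were called. Smaller lists, smaller effects and genes that share clusters were not simulated, so these rates do not carry over to them. Alternatives were other overlap rules, windows, stitching distances, thresholds and TSS choices, and each replicate list or the pooled list in place of the replicated list. For marking and breadth, backgrounds were also matched on CpG density within 500 bp of the TSS.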

Results

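H3K4me2 ChIP-seq peaks of hindbrain at embryonic day 16.5 were compared between 2 biological replicates, and then set against genes. The replicate 1 list held 52491 peaks covering 51.4 Mb and the replicate 2 list 43082 peaks covering 45.3 Mb, or 48.3 ± 4.31 Mb (SD, n = 2). The replicated list held 42682 peaks covering 50.8 Mb, 1.87% of the genome. Its median peak width was 799 bp and its median enrichment, as the authors gave it, was 10.03. The widest peak was 47931 bp.

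Most marked sequence was shared by the replicates. Of the replicate 2 peaks, 90.3% (95% Wilson interval 90.0 to 90.6%) were found in replicate 1, and of the replicate 1 peaks 67.8% (67.4 to 68.2%) were found in replicate 2. Random placement gave means of 1.799% and 1.73%. The base pair Jaccard index was 0.788, against a highest value of 0.0108 among 100 placements. The 16903 replicate 1 peaks not found in replicate 2 had a median width of 246 bp and a median enrichment of 3.33, against 979 bp and 14.8 for those found. Across the 35706 pooled peaks with a peak of both replicates, enrichment ranked alike (Spearman rho 0.900). That correlation is across peaks, which are not independent replicates.

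Promoter peaks, which overlapped 1 kb either side of a TSS, were 42.3% of replicated peaks (41.9 to 42.8%), where random placement gave 3.28%. Counted at their full width, part of which can lie outside that window, they held 67.7% of the marked base pairs. The promoter share was 36.7% in the replicate 1 list and 45.2% in the replicate 2 list. Introns held 30.2% of replicated peaks, intergenic sequence 21.7% and exons 5.72%, where placement gave 41.4%, 51.9% and 3.46%. The median width of intronic peaks was 446 bp and that of intergenic peaks 509 bp. Of replicate 1 peaks found in replicate 2, 50.6% lay at promoters, against 7.38% of those not found (odds ratio 12.9). The same shares for replicate 2 were 49.0% and 9.75% (odds ratio 8.88). Both Fisher exact p-values were below the smallest number that double precision holds.

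Of the 21851 protein-coding genes, 14494 (66.3%) had a marked promoter in the replicated list, and 66.3 ± 0.485% (SD, n = 2) in the replicate lists. Both replicates marked 14367 genes, replicate 1 alone marked 189 and replicate 2 alone 39. Breadth ranked alike across the genes marked in both (Spearman rho 0.970, across genes). Among list members, 9 were marked in 1 replicate only. Hoxa10, Hoxc8, Lhx3, Olfr452, P2ry12, Phox2b, Prdm14 and S100b were marked in replicate 1 and Myh7 in replicate 2.

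Most neural gene lists were marked in full or nearly so. All 16 pan-neuronal genes, all 18 synaptic genes, all 20 axon guidance genes and all 15 radial glia genes had a marked promoter, against about 66.3% of all genes. So did the 13 inhibitory and the 11 excitatory neuron genes, the 13 genes each of the Sonic hedgehog and Notch pathways, the 16 cell cycle and 16 housekeeping genes, the 20 forebrain transcription factors and the 15 Hox genes of paralog groups 1 to 5. Of the granule cell lineage 14 of 15 were marked, all but Gabra6, a receptor subunit of mature granule cells. These 13 lists were marked more often than other genes by Fisher exact tests, with adjusted p from 0.00245 to 0.0438. Counting only gene 5-prime ends kept 9 of them, without the forebrain, inhibitory, Notch and synaptic lists. Counting only peaks of at least median enrichment kept 8, and a 2500 bp window kept 12, without the granule list, and added the hindbrain factors (adjusted p = 0.00274) and cranial motor neuron genes (adjusted p = 0.0236, both Fisher exact tests), each marked in full. When the background was matched on CpG density, 1 of the 13, the pan-neuronal list, stayed higher (adjusted p = 0.0371, list permutation test). Matched lists were marked at 100% for axon guidance, Sonic hedgehog, Notch, cell cycle and housekeeping genes, so no higher share was possible there. The synaptic, radial glia, inhibitory, excitatory, forebrain and Hox groups 1 to 5 lists were themselves at 100%. Their matched medians ran from 86.7% (Hox) to 93.3% (radial glia). They could not lie higher and did not pass, so their lost calls do not show that CpG density accounts for all of their marking.

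There were 7 lists marked less often than other genes, of other tissues, of blood and microglia, and of chemosensory receptors. Liver genes had 1 of 14 marked (Apob, with Afp and Ahsg unmarked; adjusted p = 7.29e-05, Fisher exact test). Striated muscle genes had 4 of 17 (Acta1 and Ckm unmarked; adjusted p = 0.00245, Fisher exact test). Pluripotency and germline genes had 3 of 12 marked, Dazl, Prdm14 and Tdrd1 (adjusted p = 0.00950, Fisher exact test). Erythroid genes had 3 of 11, Epor, Klf1 and Gypa (adjusted p = 0.0168, Fisher exact test), and microglia genes 3 of 12 (adjusted p = 0.00950, Fisher exact test). Hexb, a lysosomal enzyme gene, had the widest mark of the microglia list, and Aif1 and C1qa were unmarked. Olfactory receptors had 3 of 1133 and vomeronasal receptors 1 of 330 marked. Against CpG-matched lists the liver, muscle, erythroid and microglia lists did not pass, with adjusted p of 0.367, 0.181, 0.873 and 1 (list permutation test). Liver genes were marked at 7.14% against 21.4% in matched lists and muscle genes at 23.5% against 47.1%, while erythroid genes stood at 27.3% against 18.2% and microglia genes at 25% in both. With a 2500 bp promoter window muscle genes were marked at 58.8% and the list was no longer called (adjusted p = 0.526, Fisher exact test).

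Other lists did not pass the marking test. Endothelium and pericyte genes had 8 of 12 marked (Cdh5 and Pecam1 unmarked), choroid plexus genes 8 of 12 (Aqp1 and Folr1 unmarked), meninges 10 of 12 (Ptgds and Slc13a4 unmarked) and keratinocyte genes 6 of 12 (Dsg3 and Ivl unmarked). Oligodendrocyte genes had 8 of 12, with Mag and Mog unmarked. Astrocyte genes had 11 of 12, with Gfap unmarked. Serotonergic genes had 10 of 11 (Ddc unmarked), noradrenergic 5 of 9 (Dbh and Ddc unmarked), Purkinje lineage 13 of 14 (Pcp2 unmarked) and cranial motor neuron genes 11 of 12 (Phox2b unmarked).

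**Figure D1:**
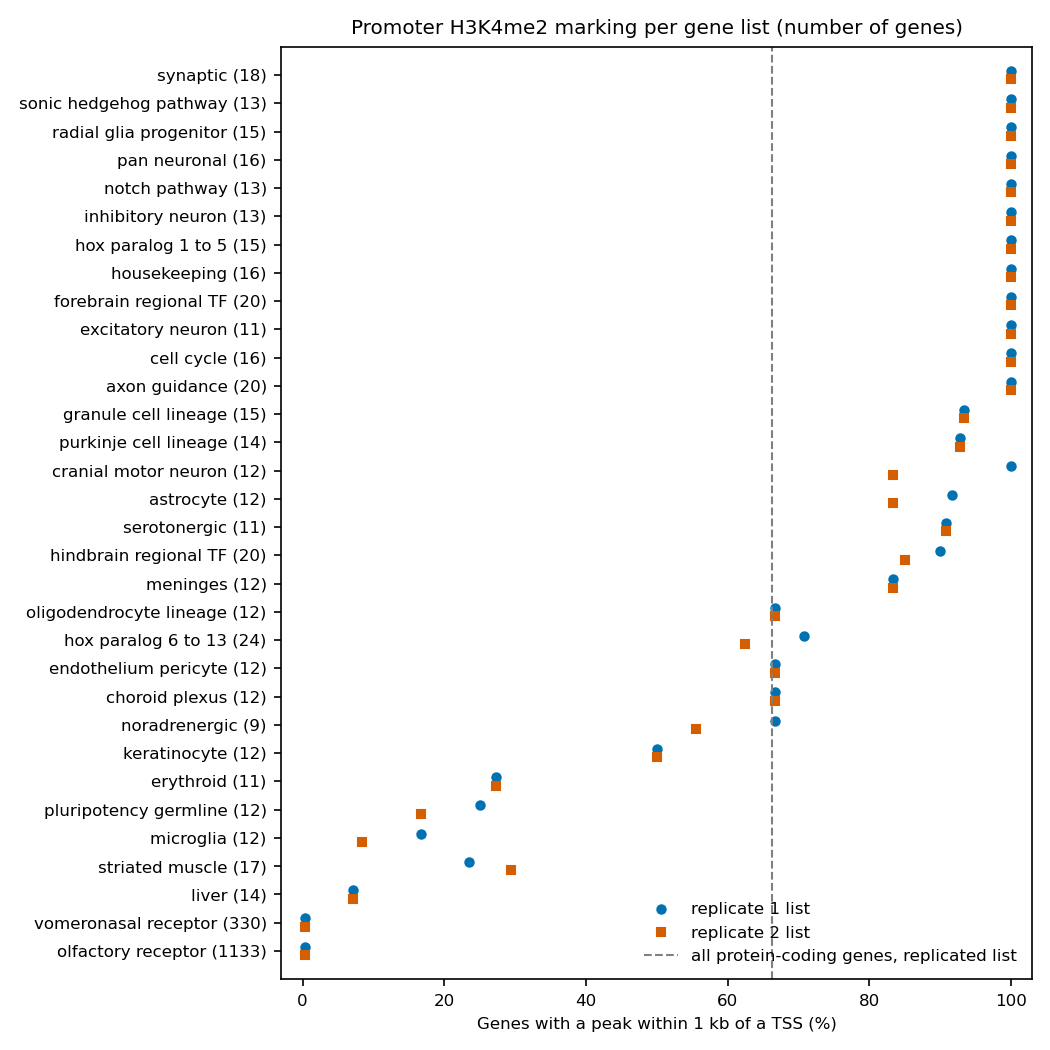
Share of genes with a peak within 1 kb of a TSS (%, horizontal axis) for each of the 32 gene lists, with the number of genes in brackets. Circles are the replicate 1 list, squares the replicate 2 list, and the dashed line is the 66.3% of all protein-coding genes in the replicated list.

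Among marked genes, H3K4me2 was broadest in Hox, neuronal, progenitor and hindbrain lists. Median breadth was 8026 bp for Hox genes of groups 1 to 5, 7522 bp for inhibitory neuron genes, 6926 bp for hindbrain transcription factors, 5996 bp for radial glia and 5696 bp for pan-neuronal genes, against about 2515 bp for random lists. In all, 14 lists were broader than random lists, with adjusted p from 0.000545 to 0.0123 (list permutation test), and each stayed so with matched CpG density and in either replicate list. The housekeeping list was among them, at 4058.5 bp (adjusted p = 0.00318, list permutation test). The synaptic list had 4270 bp and the Purkinje list 4023 bp, so breadth above random lists was not confined to neural lists. With a 2 kb window 11 of the 14 stayed, without the excitatory, housekeeping and Sonic hedgehog lists, and with a 10 kb window 13, without the Purkinje list. Per replicate, the median was 7800 ± 754 bp (SD, n = 2) for Hox groups 1 to 5 and 6851.5 ± 692 bp for inhibitory neuron genes. Members of a list were ranked on the replicated list, and their values are replicate means. The broadest inhibitory genes were Gad1, which makes GABA (9759.5 ± 75.7 bp, SD, n = 2), Slc32a1, the vesicular transporter of GABA and glycine (9152.5 ± 30.4 bp), and Slc6a5, a glycine transporter (8778 ± 182 bp). In the excitatory list they were Lmx1b (8633.5 ± 780 bp), Ebf2 (8272.5 ± 342 bp) and Tlx3 (7503 ± 1568 bp). By replicate means Uncx, named after its values were seen, lay above Tlx3 (8216.5 ± 151 bp). Lmx1b also led the serotonergic list, with Insm1 and Gata3.

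Pan-neuronal breadth was led by Celf4 (8107 ± 226 bp), Elavl4 (7970 ± 105 bp) and Tubb3, neuronal beta tubulin (7104 ± 120 bp). Pax6, a regulator of progenitors and of cerebellar granule cells, covered 9490 ± 74.95 bp, and the Notch targets Hes1 and Hes5 covered 6737 ± 392 and 6641 ± 147 bp. Dll1, a Notch ligand, covered 7470 ± 274 bp. In the granule lineage Zic1 covered 9734.5 ± 82.7 bp, Zic4 9013 ± 181 bp and Cbln1 8348.5 ± 548 bp. In the Purkinje lineage Lhx1 filled the whole window of 10001 bp in both replicates, Lhx5 covered 8971.5 ± 213 bp and Skor2 4396 ± 844 bp. Ptch1, the Sonic hedgehog receptor, covered 9499 ± 141 bp, and Mycn 6747 ± 63.6 bp and Boc 5352.5 ± 19.1 bp. Axon guidance breadth was led by Sema6a, Nrp1 and Unc5c, synaptic breadth by Dlg4, Syngap1 and Nrxn1, and astrocyte breadth by Nfib, Nfia and Slc1a2.

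There were 7 lists narrower than random lists, microglia, meninges, noradrenergic, pluripotency and germline, olfactory receptor, forebrain transcription factor and Hox groups 6 to 13. Their medians ran from 303 bp (microglia) to 1721 bp (meninges), with adjusted p from 0.000545 to 0.0483 (list permutation test). The microglia median rests on 3 marked genes, and was 949 bp in the replicate 1 list and 1606 bp in the replicate 2 list, where 2 and 1 were marked. Part of this set depended on the settings. With the replicate 1 list alone 3 of the 7 stayed, and the forebrain, meninges and germline lists did not pass. With the replicate 2 list alone 4 stayed, and the noradrenergic list did not pass. Microglia genes in either list, and germline genes in the replicate 2 list, had too few marked members for the test. With matched CpG density 4 stayed, and the meninges (1721 against 2552.5 bp in matched lists, adjusted p = 0.0583), noradrenergic (1456 against 2300 bp, adjusted p = 0.0552) and olfactory receptor lists (477 against 1620 bp, adjusted p = 0.0552) stayed below matched lists but did not pass (list permutation test). With a 2 kb window all 7 stayed, and the keratinocyte and striated muscle lists joined them. Striated muscle also joined with the replicate 2 list alone. The pooled list lost meninges and noradrenergic, and gene 5-prime ends lost noradrenergic and olfactory receptor. With a 10 kb window 3 stayed, without the forebrain, Hox, meninges and noradrenergic lists.

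Most neural lists had more distal peaks than random lists, and so had the forebrain and housekeeping lists. Random lists averaged about 1.25 distal peaks within 50 kb of a TSS. They were drawn from all protein-coding genes, marked or not, and were not matched on CpG density for this test. Hox groups 1 to 5 averaged 7.13, excitatory neuron genes 6, radial glia 5.87, granule lineage 5.80, hindbrain transcription factors 5.75 and inhibitory neuron genes 5.46, each with adjusted p = 0.000640 (list permutation test). Hox groups 6 to 13 averaged 5.21, with the same adjusted p. Neighbouring Hox genes count the same distal peaks (14 each at Hoxa3, Hoxa4 and Hoxa5). Random lists do not share peaks in this way, so the p-values of both Hox lists can be too small. In the replicate 1 and replicate 2 lists the means were 11.4 and 11.2 for Hox groups 1 to 5, 7.36 and 7.09 for excitatory genes and 8.08 and 5 for inhibitory genes. For the Hox and excitatory genes both lay above the replicated list, so the count depends on the peak list. With the replicated list 16 lists were higher and 2 lower, the olfactory receptors at 0.121 and the vomeronasal receptors at 0.0879. All 16 stayed in either replicate list, and with gene 5-prime ends 15 did, without the astrocyte list. In the replicate 1 list the Purkinje list joined them, at 3.71 against 1.64 for random lists of its size (adjusted p = 0.0207, list permutation test). With a 20 kb window the Purkinje (adjusted p = 0.00452) and cranial motor neuron lists (adjusted p = 0.0232) joined, both by the list permutation test.

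Across the Hox clusters H3K4me2 was more extensive over paralog groups 1 to 5 than over 6 to 13. All 15 genes of paralog groups 1 to 5 were marked and 16 of 24 genes of groups 6 to 13 (p = 0.0146, two-sided Fisher exact test). Mean breadth over all genes, unmarked ones included, was 7574.9 ± 2762 bp and 2104.5 ± 2844 bp (SD over genes). It was 3.60 times as large in the former (p = 2.0e-05, two-sided permutation test, the smallest that test can give). Counting only the 5-prime end of each gene record gave p = 0.0574 for marking (Fisher exact test). Neighbouring Hox genes share clusters and peaks, so genes are not independent and these p-values can be too small. Hoxb3 and Hoxb4 each covered 9968 ± 46.7 bp (SD, n = 2), Hoxd3 9879.5 ± 107 bp and Hoxa2 9713 ± 119 bp. Hoxa6 (8047.5 ± 1531 bp), Hoxb6 (7688.5 ± 788 bp) and Hoxb7 (6677 ± 2277 bp) were the broadest of groups 6 to 13. Hoxb1 (818 ± 324 bp) and Hoxd1 (1632.5 ± 88.4 bp) were the narrowest of groups 1 to 5. The 8 unmarked genes were Hoxa9, Hoxa10, Hoxa11, Hoxc9, Hoxc11, Hoxc12, Hoxd10 and Hoxd12.

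**Figure D2:**
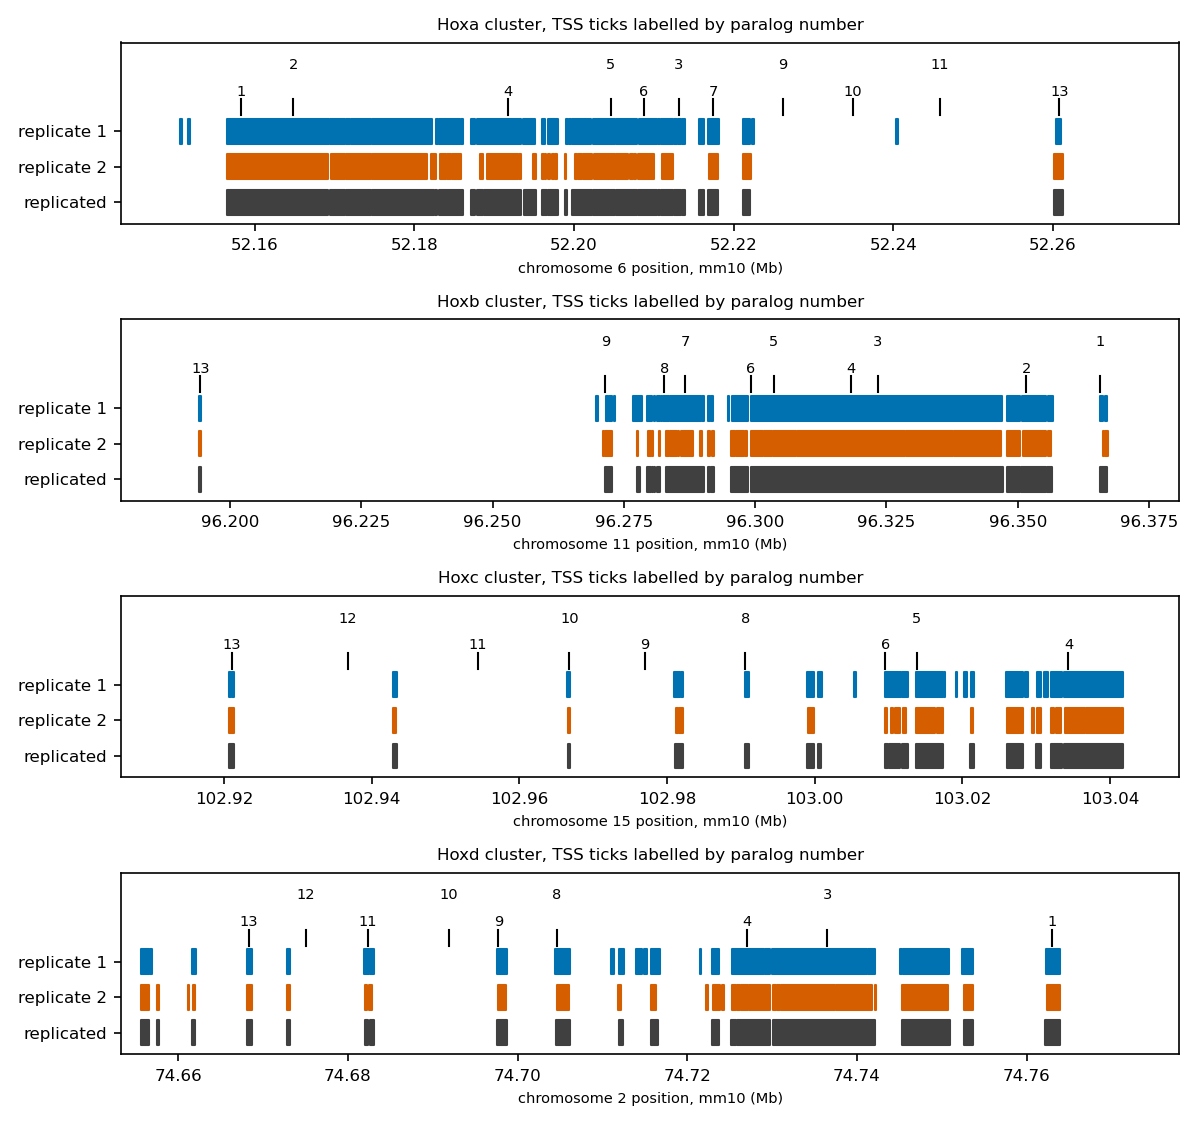
Peaks of the replicate 1, replicate 2 and replicated lists across the Hoxa, Hoxb, Hoxc and Hoxd clusters (mm10 position in Mb, horizontal axis), with TSSs as ticks labelled by paralog number. Peaks form long blocks around Hoxa1 and Hoxa2, from Hoxb2 to Hoxb6 and at Hoxd3 and Hoxd4. Around Hoxa4 to Hoxa6 the replicated list has 19 peaks over 26.8 kb, of which replicate 2 peaks cover 61.1%. Coverage is also wide at Hoxb7, Hoxb8, Hoxc4 and Hoxc5. Peaks are short and separate around groups 9 to 13.

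Regional transcription factors of hindbrain and forebrain differed in breadth, and their marking did not pass the test for a difference. Of 20 hindbrain factors 17 were marked, and all 20 forebrain factors (p = 0.231, two-sided Fisher exact test). At gene 5-prime ends 17 of each were marked, and with a 2500 bp window all 20 hindbrain factors. Mean breadth over all 20 genes of each list, unmarked ones included, was 5512.2 ± 3066 bp for hindbrain and 2304.7 ± 1470 bp for forebrain factors (SD over genes). The difference was 3207.5 bp and the ratio 2.39 (p = 0.000280, two-sided permutation test). Replicate 1 alone gave a difference of 2776 bp and replicate 2 alone 3077.9 bp. Its size depended on the breadth window. A 2 kb window gave 1047 bp and a ratio of 1.62 (p = 0.00716, two-sided permutation test), and a 10 kb window 4831 bp. The broadest hindbrain factors were Irx2 (9320 ± 38.2 bp, SD, n = 2), Irx5 (9274 ± 15.6 bp) and Lmx1b (8633.5 ± 780 bp). Dbx1 and Pax5 were among the unmarked. The broadest forebrain factors were Lhx2 (5349.5 ± 2299 bp), Satb2 (5037 ± 206 bp) and Otx1 (4385.5 ± 1565 bp).

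The longest domain, 61.1 kb on chromosome 11 (96295428 to 96356515), held the TSSs of Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxb6, and was 21.0% exonic, 54.8% intronic and 24.2% intergenic. Replicate 1 peaks covered 96.2% of it and replicate 2 peaks 93.4%. The next longest, 36.0 kb on chromosome 9 (91349174 to 91385142), held Zic1 and Zic4, which encode zinc finger regulators of the cerebellum. Other domains among the 20 longest held Hoxa1 and Hoxa2 with 5730596B20Rik (29.7 kb, chromosome 6, 52156482 to 52186134), Meis2 (29.0 kb, chromosome 2, 116047703 to 116076677) and Bcl11a with A830031A19Rik (27.5 kb, chromosome 11, 24073312 to 24100769). The rest with a protein-coding TSS held Ebf3, Hoxa3 to Hoxa6 with Gm28308, Nr2f2, Pax6, Nfib, Nr2f1, Lhx1 with Aatf, Pou3f3, Mn1, Tshz1 with Zadh2, and Zfhx3. Domains of at least 4682 bp made up the longest 5%, 1584 of 31699. They held a TSS of 1628 genes, 11.2% of marked genes. Pan-neuronal genes lay in them in 13 of 16 cases, axon guidance genes in 15 of 20, Hox groups 1 to 5 in 12 of 15, radial glia genes in 12 of 15 and hindbrain factors in 12 of 17. In all 13 lists were enriched, with adjusted p from 1.54e-09 to 0.0113 (Fisher exact test), and none was depleted. With the replicate 2 list alone the Purkinje list was not called. Without stitching 11 of the 13 stayed, without the inhibitory and Purkinje lists. Stitching within 3 kb gave 16 lists, without the Purkinje list and with the housekeeping, oligodendrocyte, serotonergic and Hox groups 6 to 13 lists.

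Distal peaks held more CTCF, RFX and ZIC sites, and more of 1 type of E-box, than their flanks. The E-box called NEUROD or ASCL1 type was the sequence CAGCTG, and the ATOH1 type was CAGATG. These names label the sequences only, and which factors bind them was not tested. Over 19335 pairs of windows, the CTCF core motif was in 2.75% of peaks and 0.305% of flanks (ratio 9.02), the RFX motif in 0.326% and 0.0414% (ratio 7.88), the ZIC motif in 23.8% and 11.7% (ratio 2.03), and the NEUROD or ASCL1 type of E-box in 28.9% and 17.2% (ratio 1.69). The NFI motif was in 0.145% and 0.0103%. The largest adjusted p of these 5 motifs was 1.88e-06 (exact McNemar test). The homeobox motif did not pass the test (11.5% and 11.1%, adjusted p = 0.230, exact McNemar test), nor did the ATOH1 type of E-box (29.4% and 28.8%, adjusted p = 0.213, exact McNemar test). Lower in peaks were the SOX motif (44.2% and 45.6%, adjusted p = 0.0150), the AP-1 motif (6.11% and 6.72%, adjusted p = 0.0249) and the GATA motif (3.99% and 5.14%, adjusted p = 1.64e-07), all by exact McNemar tests. The GATA motif was included as a control, so over all pairs the test also called a control. Peak windows had 51.2% GC and flanks 44.8%. Among 5052 pairs of like GC content the homeobox motif was in 15.004% of peaks and 8.06% of flanks, a ratio of 1.86 (adjusted p = 1.55e-27, exact McNemar test), the MEF2 ratio was 1.97 (adjusted p = 0.00383, against 1.15 and 0.230 over all pairs, exact McNemar test), and the ZIC ratio was 1.31. There the AP-1 ratio was 0.824 and the SOX motif was higher in peaks (ratio 1.07, adjusted p = 0.00527), and the GATA motif did not pass (4.65% and 4.33%, adjusted p = 0.514), by exact McNemar tests. In these pairs the NEUROD or ASCL1 type of E-box had a smaller ratio of 1.28 (25.7% and 20.1%, adjusted p = 3.36e-11, exact McNemar test). The NFI motif was in 0.119% and 0% (adjusted p = 0.0406, exact McNemar test). The CTCF ratio was 10.1 and the RFX ratio 9.67.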

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

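The alternatives with GC-matched motif windows, with a stricter q for peak numbers and with an adjusted hindbrain and forebrain difference were chosen after seeing the data. The share of replicate 1 peaks found in replicate 2 was 73.02% with any overlap, 61.3% with reciprocal overlap, 70.0% at −log10 q of at least 2 and 79.0% with equal numbers of top peaks. The replicate 2 shares were 93.1%, 74.7%, 92.2% and 87.0%. The Jaccard index was 0.795 at the stricter q and 0.810 with top peaks. Rank agreement was 0.900 with half-covered pooled peaks and 0.928 for −log10 p. The promoter share was 49.5% with a 2500 bp window and 74.0% for peaks of at least median enrichment. Marked genes were 65.6% with 500 bp, 67.6% with 2500 bp and 62.8% at median enrichment. Lists marked more often fell from 13 to 10 at gene 5-prime ends (9 of the 13 and the Purkinje list), to 8 at median enrichment and to 1 with matched CpG density, and lists marked less often from 7 to 4 with matched CpG density (3 of the 7, and Hox groups 6 to 13 newly called). Most lists that lost the higher call with matched CpG density were marked in full, so they could not lie higher. Narrower lists numbered 7, 9 with a 2 kb window, 3 with a 10 kb window, 4 with matched CpG density, and 3 to 5 when either replicate was left out, where lists with under 3 marked genes had no test. Broader lists fell from 14 to 11 within 2 kb and to 13 within 10 kb. Without replicate 2, cranial motor neuron and hindbrain lists joined those marked more often. Lists enriched in broad domains numbered 13, 11 without stitching and 16 with 3 kb. Of the 20 longest domains 11 were among the 20 longest without stitching. Motifs higher in peaks rose to 9, MEF2 among them, and lower ones fell to 1, with GC-matched windows. The difference of Hox marking was 30.8 points at gene 5-prime ends, no longer past the threshold.

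Some single lists and motifs changed direction. Erythroid genes (27.3% marked) lay above CpG-matched lists (18.2%). Hox groups 6 to 13 were marked at 33.3% at median enrichment and at 66.7% against 95.8% in CpG-matched lists, below the background in both. Within 10 kb, median breadth was 2801 bp for forebrain factors and 3066.5 bp for Hox groups 6 to 13, above random lists. With GC-matched windows the ratios were 1.07 for SOX and 1.54 for PBX-HOX, which passed, and 1.07 for GATA, which did not (adjusted p = 0.514, exact McNemar test). The cause was not tested, except that matching itself removes CpG or GC differences. Over all alternatives fixed before the data were examined, 108 values of the main comparisons stayed within their error, count or threshold limits, 24 moved and 1, the Hox marking, weakened past its threshold. Of the values of single lists and motifs 960 stayed, 50 weakened past the threshold, 22 strengthened past it and 5 changed direction, and the 3 motif ratios above come from an alternative chosen after seeing the data. Depth is unknown, which limits what can be said of weak peaks.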

Other observations

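Of the tests here, those of sequencing depth and of the files behind the calls for the replicate 1 peaks, and the hindbrain and forebrain difference after a fit on CpG density and number of TSSs, were chosen after seeing the data. No biological explanation of the replicate 1 peaks was tested.

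Some long H3K4me2 domains without a protein-coding TSS, 15 of 116, held microRNA genes, which are named here after their values were seen. All 3 loci of miR-9, a microRNA of neural progenitors, lay in such domains among the 20 longest. Mir9-2 lay in 33.4 kb on chromosome 13 (83712996 to 83746419), Mir9-1 in 24.8 kb on chromosome 3 (88198199 to 88223045) and Mir9-3 in 22.3 kb on chromosome 7 (79495909 to 79518249). The 3 loci of miR-124, a neuronal microRNA, also lay in such domains, Mir124a-2 in 18.1 kb, Mir124a-1 in 11.6 kb and Mir124a-3 in 8.25 kb. Mir137 lay in 6.96 kb and Mir125b-1 in 12.96 kb. Replicate 1 and replicate 2 peaks covered 91.9% and 94.6% of the Mir9-2 domain.

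Among the 116 broad domains without a protein-coding TSS, 15 held a microRNA gene, where 100 random placements of the same lengths gave a mean of 0.74 and a highest value of 3. Of the 1468 broad domains with a protein-coding TSS, 47 held one. Domain length alone is argued against, since 15 lay above every placement. The placements were matched on length and the pattern had been seen in these same domains, so the value speaks to length only. Unannotated protein-coding starts stay open. Of the 116 domains 8.62% lay within 2 kb of an annotated protein-coding TSS, but the domains were chosen for holding none, so this value tests nothing. A candidate explanation is that these domains mark promoters of active microRNA host transcripts, which was not tested with expression.

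The forebrain transcription factors were all marked, yet narrow, in a tissue that the labels call hindbrain. The full marking depended on the settings, with 17 of 20 at gene 5-prime ends and 65% at median enrichment. CpG density may account for much of the marking, since CpG-matched lists had a median of 90% marked, against 66.3% of all genes. Whether it accounts for all of it cannot be told. The list was at 100%, and even so the two-sided share was 0.225, so no value could have passed. CpG density is argued against for the narrow breadth, where the median of 1623 bp lay below the CpG-matched median of 2390.25 bp (two-sided share 0.00020). The narrow breadth itself depended on the list and window. With the replicate 1 list alone the median was 2122.5 bp and did not pass (adjusted p = 0.236, list permutation test), and with a 10 kb window it was 2801 bp, against 2796.5 bp for random lists. The broader mark of hindbrain factors kept 93.0% of its difference after a fit on CpG density and number of TSSs. A small share of forebrain cells stays open, since median enrichment at the forebrain factors, 17.1, lay below the CpG-matched 28.7 (two-sided share 0.00020), but hindbrain factors lay below theirs too, at 21.1 against 30.2, so this value does not single out forebrain cells.

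The replicate 1 list held peaks that replicate 2 lacked. Extra weak calls may account for part of them, since with equal numbers of top peaks 79.0% of replicate 1 peaks were found in replicate 2. Yet 78.5% of the replicate 1 peaks not found had a −log10 q of at least 2. With that q in both lists 70.0% were found, against 67.8% in the full lists, so calls below that q account for little of the difference. Deeper sequencing of replicate 1 may also contribute, since at shared peaks of like enrichment its −log10 p was 1.53 times as large, a value that a deeper control would raise as well. Whether the calls used different controls is not known. The replicate 1 call used 2 further files of unstated content and the replicate 2 call 1 of the same files, so any effect of them cannot be told apart from the replicate.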
